A study of Mus musculus with 19 samples.

How the data were processed

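Gene expression was measured on Illumina bead arrays in left ventricular myocardium of male MerCreMer mice, which carry a Cre recombinase fused to a mutated estrogen receptor under a cardiac myosin heavy chain promoter, so that tamoxifen activates Cre in cardiomyocytes. Per the labels the mice were back-crossed to C57Bl6/J, were 12 to 20 weeks old and received tamoxifen free base in peanut oil by intraperitoneal injection, 1 mg (40 mg/kg) a day for up to 5 days. The labels of the day 10 and day 28 samples speak instead of tamoxifen followed by a normal diet, as if it were given in the diet, although the same diet is stated for all mice. The route is given here as in the protocol. RNA was extracted with TRIzol, had an RNA integrity number above 9, and was amplified to biotinylated cRNA.

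The values used are the deposited intensity of each of 25697 probes on 19 arrays, on a linear scale. The authors had quantile-normalized these values between arrays: the sorted values of all 19 columns were identical, from 116.032 to 57814.4 with a median of 191.479 on every array. The labels do not state the program that made them or whether background was subtracted. A second deposited table holds scanner signals and detection p-values that are not normalized, but its 38 columns carry laboratory codes that match no sample label, so it was not used. No detection calls were therefore available, and the settings laid down for that case before the data were examined were used. These were limma's normexp background correction with an offset of 50, log2, and removal of probes below the 25th percentile of mean intensity (162.92). Quantile normalization was also laid down but was not run again, the deposited values being already quantile-normalized. That left 19272 probes, of which 18095 had 1 gene symbol (12938 genes) and 1177 had none. Of the 25697 probes, 23978 had 1 symbol, 0 had several and 1719 had none, and 23962 had a gene identifier found in the mouse RefSeq table (GRCm38.p6), which was used for names alone.

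The 19 arrays fall into 5 groups by their labels: control (5 arrays), day 2 (4), day 3 (3), day 10 (3) and day 28 (4). The arrays of a group were treated as separate samples, as their numbers in the labels imply, and the p-values measure the spread between them. A linear model with 1 mean per group was fitted to all 19 arrays in limma 3.58.1 under R 4.3.3, with moderated variances (prior degrees of freedom 9.66, residual degrees of freedom 14). For each of 7 comparisons, 2-sided p-values were adjusted by the Benjamini-Hochberg method over the 19272 probes, and a probe was called at an adjusted p under 0.05. No fold threshold was set. The number of arrays limits the precision of every value.

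Before the data were examined, 31 gene lists were written down: 22 lists of pathways and functional collections and 9 lists of cell type markers. Each was tested with limma's camera at a preset correlation between genes of 0.01, on 1 probe per gene (the probe with the highest mean), with adjustment over the 31 lists of a comparison, and again with an estimated correlation. Each list also has its count of called members over all probes tested and its count adjusted over the list alone. The genes named were fixed by rule: the 8 genes with the largest rise and the 8 with the largest fall among those called, in each comparison with control and in day 28 against day 10, with 3 and 3 for consecutive times, plus Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Ppargc1a, Cdkn1a, Col1a1 and Esr1. Clone names and predicted models were passed over. Members of a list given as examples are those with the smallest adjusted p.

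All fold changes are on log2(corrected intensity + 50), a scale that understates the fold change of dim genes. The highest log2 value in the table is 15.8, and genes close to it are compressed. On simulated data with the spread of these arrays, 83% to 96% of planted 2-fold changes and 99% to 100% of 4-fold changes were called, depending on the comparison. There were 2 to 12 false calls, and a planted list was found with 0 of 20 unchanged lists called. The simulated noise was independent between genes and had no structure within groups. In the real data the estimated correlation exceeded the preset one in 210 of 217 list tests. The simulation therefore cannot tell how often lists are called falsely here.

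Alternatives tried were no background correction (which is also the log2 of the authors' own values), no filter, fitting the groups of a comparison alone, the replicate number as a block, trended and robust variances, array weights, a 2-fold threshold, 1 probe per gene, an estimated correlation in the list test, and leaving out each array in turn. An offset of 16, a filter at the 50th percentile, controls 1 to 3 alone and each of the 10 pairs of controls were added after the data were seen. The labels give no slide, date or batch. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.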

Results

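Left ventricles of MerCreMer mice were profiled before tamoxifen (control, n = 5), during the daily injections at day 2 (n = 4) and day 3 (n = 3), at day 10 (5 days of injections and 5 further days, n = 3) and at day 28 (5 days of injections and 23 further days, n = 4). The series describes a transient cardiomyopathy with the deepest dysfunction at day 10 and recovery after about 4 weeks. The comparisons ask which genes changed as the heart failed and which had returned by day 28. No vehicle group and no tamoxifen-treated mice without Cre are among the samples, so that tamoxifen, Cre activity and time cannot be told apart. Every array had the same median intensity, 191.479, after the authors' normalization.

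The first 2 principal components held 40.1% and 24.2% of the variance, and the groups separated along them in part. The day 10 arrays lay farthest along component 1 (54.3 to 72.7) and the day 3 arrays lowest on component 2 (-48.2 to -45.6). The 5 controls were not alike. Controls 4 and 5 scored 20.5 and 20.1 on component 2, beside the day 28 arrays (21.1 to 23.1), whereas controls 1 to 3 scored 1.59 to 4.38.

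**Figure D1:**
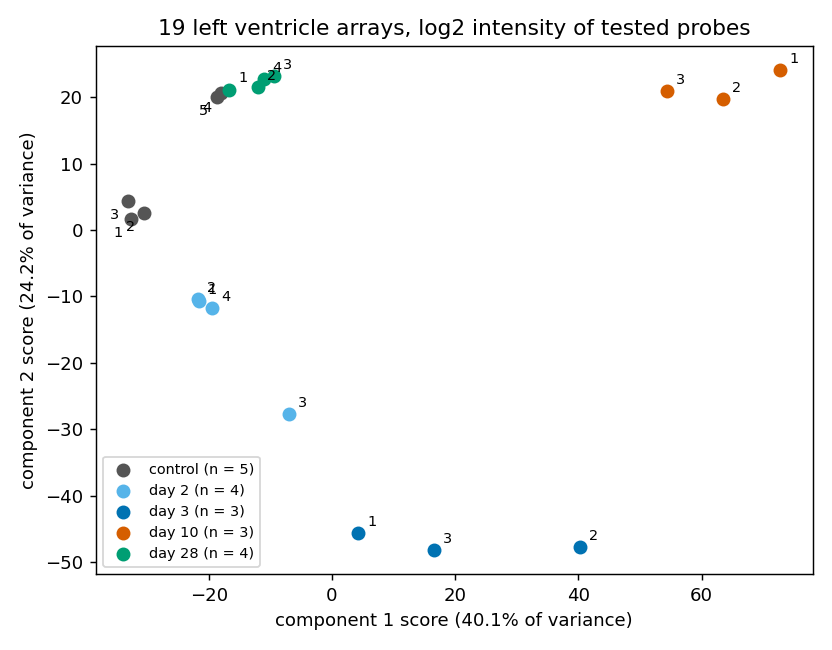
Scores of the 19 arrays on principal components 1 and 2 (40.1% and 24.2% of the variance) of log2 intensity; each point is an array, coloured by group and numbered by replicate. Controls 4 and 5 lie next to the day 28 arrays, apart from controls 1 to 3.

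Of the 19272 probes tested, 1279 were called at day 2 (654 up, 625 down), 5470 at day 3 (2708 up, 2762 down), 6894 at day 10 (3409 up, 3485 down) and 347 at day 28 (214 up, 133 down), each against control. Changes of at least 2-fold numbered 144, 1292, 2134 and 69.

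**Figure D2:**
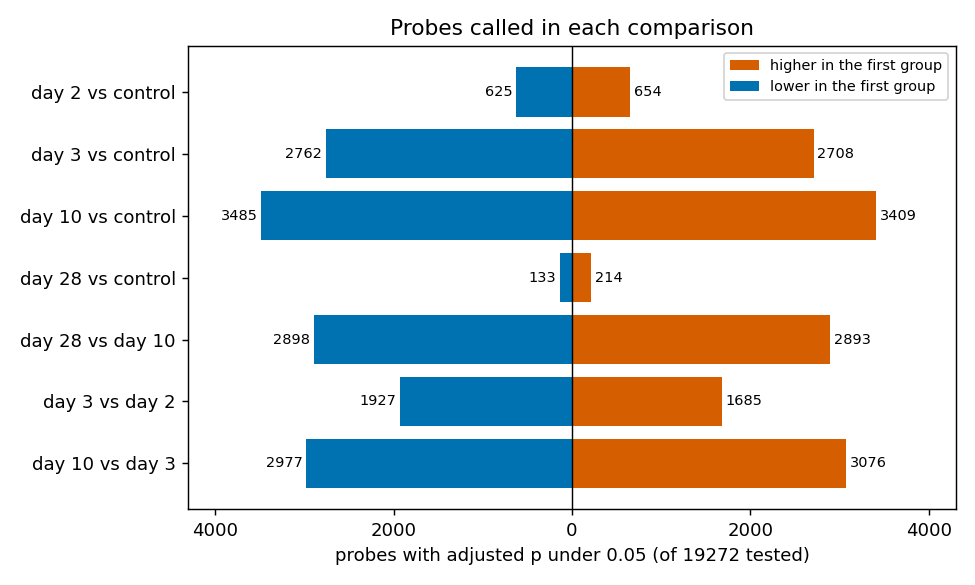
Number of probes called in each of the 7 comparisons (horizontal axis, probes of 19272 tested), higher in the first group to the right and lower to the left. Day 10 against control had the most calls (6894) and day 28 against control the fewest (347).

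At day 2 transcripts of skeletal muscle troponins and the stress gene Cdkn1a were higher in the samples than in control. The mitochondrial coactivator gene Ppargc1a and some calcium handling and ion channel genes were lower, while the calcium channel gene Cacna1h was higher. Tnnt1, the slow skeletal troponin T (probe ILMN_2460136), rose 6.63-fold, from 9.60 ± 0.29 (SD, n = 5) in control to 12.33 ± 0.70 (SD, n = 4) on the log2 scale. Tnni2 and Tnnt3, the fast skeletal troponins I and T, rose 4.03-fold and 3.41-fold, the latter from a control value below the median of all probes. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 3.67-fold (log2 1.88 ± 0.34 SE, adjusted p = 0.00105). Ppargc1a, a coactivator that drives mitochondrial gene expression, fell by 2.22 ± 0.37 SE on the log2 scale (adjusted p = 0.000463), from 11.33 ± 1.01 (SD, n = 5) to 9.11 ± 0.64 (SD, n = 4).

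The other large rises at day 2 were those of Gpnmb, a glycoprotein gene of macrophages and stressed lysosomes (log2 2.06, 2 of 4 probes), the innate immune regulator Nlrc3 (2.00), the decoy death receptor gene Tnfrsf22 (1.77) and Cacna1h, a T-type calcium channel (1.76). The other large falls were those of the orphan receptor gene Gpr22 (-2.29), the L-type calcium channel subunit gene Cacnb2 (-2.01), the integrin gene Itgb6 (-2.00), the splicing regulator gene Rbfox1 (-1.67), the potassium channel subunit gene Kcnv2 (-1.66), Yipf7 (-1.55) and Schip1 (-1.51). Of the 17 named genes called at day 2, 16 lay beyond every control array in 4 of 4 arrays, and Nppb did so in 1 of 4 and lay beyond the control mean in 4 of 4. Nppb, the B-type natriuretic peptide gene, rose by 0.85 (adjusted p = 0.0203). Values for Nppa (0.49), Acta1 (0.84), Myh6 (0.14), Myh7 (-0.30), Atp2a2 (-0.02) and Col1a1 (0.18) did not pass the test, and Esr1 (-0.03), part of whose coding sequence is in the transgene, was near background in every group.

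Among gene lists, calcium handling and ion channel genes fell at day 2: 10 of 23 measured members (10 adjusted over the list alone), with Gja1, the gap junction gene of ventricular muscle, at -1.44 and the potassium channel partner Kcnip2 at -1.24. The calcium handling list gave adjusted p = 6.31e-10, and adjusted p = 0.334 with an estimated correlation. Oxidative phosphorylation genes were lower, 13 of 74 (33 adjusted over the list alone), with a median of -0.34 and Ndufb11 at -0.92. The oxidative phosphorylation list gave adjusted p = 1.34e-13, and adjusted p = 0.691 with an estimated correlation. Fetal and wall-stress genes were higher, 5 of 14 (6 adjusted over the list alone). Among them were Mybpc2, also a fast skeletal muscle gene (1.66), Xirp1 (1.23) and Rcan1 (0.83). The fetal gene list gave adjusted p = 0.000559, and adjusted p = 0.691 with an estimated correlation. Fatty acid oxidation genes had 2 falls among 27 (3 adjusted over the list alone), with adjusted p = 0.00711, and adjusted p = 0.8 with an estimated correlation. Fibroblast markers had 0 called members of 15 (0 adjusted over the list alone) and a median of -0.32, with adjusted p = 0.0486, and adjusted p = 0.773 with an estimated correlation. Macrophage markers had 1 called member of 22, Gpnmb, a median of -0.04 and a mean of 0.11, and the median became 0.40 (adjusted p = 3.47e-05) with controls 1 to 3 alone.

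Ppargc1a lay at 11.3 to 12.5 in controls 1 to 3 and at 10.3 and 10.4 in controls 4 and 5, and with controls 1 to 3 alone it fell by 2.89 at day 2, 4.18 at day 3 and 2.53 at day 10. The day 2 count was 731 with controls 1 to 3 alone and 814 without day 2 replicate 3, which also took Gpnmb to 2.78-fold and the adjusted p of fatty acid oxidation to 0.26. Nppb was not called without control 3 (adjusted p = 0.0542), control 4 (0.0572), control 5 (0.0502) or day 2 replicate 3 (0.0979), nor with array weights (0.0577) or controls 1 to 3 alone (0.156). Acta1 was called without control 2 (0.0177), and fatty acid oxidation was not called without control 3 (0.0524). Fibroblast markers were not called without control 2 (0.0535), control 4 (0.147), control 5 (0.144), day 2 replicate 1 (0.162) or day 2 replicate 2 (0.0611). They were not called either without background correction (0.0593), with an offset of 16 (0.0601), a 50th percentile filter (0.112), array weights (0.0619), the replicate number as a block (0.157) or controls 1 to 3 alone (0.481).

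At day 3 the heat shock gene Hspa1a and genes of the matrix, cytokine and immediate early lists rose, Tnnt1 and Cdkn1a were again higher than in control, and calcium handling and mitochondrial genes were lower. Hspa1a, the inducible heat shock protein gene (probe ILMN_2829594), rose 30.9-fold, from 8.91 ± 1.24 (SD, n = 5) to 13.86 ± 1.29 (SD, n = 3). Cdkn1a rose 17.6-fold (log2 4.14 ± 0.37 SE, adjusted p = 6.89e-09) and Tnnt1 19.6-fold (4.29 ± 0.27 SE, adjusted p = 8.14e-11). Pln, which encodes phospholamban, the inhibitor of the cardiac calcium pump, fell by 3.50 ± 0.31 SE (adjusted p = 6.51e-09), and Ppargc1a fell by 3.51 ± 0.40 SE (adjusted p = 2.63e-07).

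Further large rises at day 3 were in Gpnmb (log2 4.78), the metalloproteinase inhibitor gene Timp1 (4.57), Tnfrsf22 (4.40), the stress transcription factor gene Atf3 (3.95) and the matrix glycoprotein gene Tnc (3.93, in 4 of its 5 probes, from a control value below the median of all probes). Further large falls were in Yipf7 (-3.79), the LIM protein gene Fhl2 (-3.35), Fgf13, a modulator of sodium channels (-3.29), Lrtm1 (-3.17), Gpr22 (-3.15) and Grb14, an adaptor of the insulin receptor (-3.04). Nppb rose by 1.45 and the skeletal actin gene Acta1 by 1.37 (adjusted p = 0.0118), and Nppa by 1.01 at the edge of the test (adjusted p = 0.0489). Of the 19 named genes called at day 3, 17 lay beyond every control array in 3 of 3 arrays, and Nppa and Acta1 did so in 0 of 3 and lay beyond the control mean in 3 of 3. Values for Myh6 (-0.16, with 1 of its 2 probes called lower), Myh7 (-0.30), Atp2a2 (-0.21), Col1a1 (0.61, adjusted p = 0.0603) and Esr1 (0.10) did not pass.

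Immediate early genes, which respond within minutes to many stimuli, rose at day 3: 16 of 21 (17 adjusted over the list alone), median 1.13, with Fos at 3.77 and Junb at 3.08. The immediate early list gave adjusted p = 5.26e-08, and adjusted p = 0.128 with an estimated correlation. Over the 10 pairs of controls its median ran from 0.89 (controls 2 and 4) to 1.35 (controls 1 and 5). Inflammatory cytokine and NF-kB target genes rose in 13 of 28 (14 up and 1 down adjusted over the list alone), with Socs3 at 3.62, Lcn2 at 3.49, Ccl7 at 3.15 and Ccl2 at 2.94. The cytokine list gave adjusted p = 8.11e-05, and adjusted p = 0.403 with an estimated correlation. Extracellular matrix genes had 15 rises and 3 falls among 38 (17 and 3 adjusted over the list alone), with Thbs1 and Ccn2 both at 2.49. The matrix list gave adjusted p = 0.000515, and adjusted p = 0.433 with an estimated correlation. In the p53 and DNA damage list 14 of 31 rose and 4 fell (15 and 4 adjusted over the list alone), with the death gene Bbc3 at 1.60 while Sesn1 (-2.38) and Ccng1 (-1.27), which are also p53 targets, fell. The p53 list gave adjusted p = 0.000318, and adjusted p = 0.128 with an estimated correlation. Genes of the ATF4 response had 10 rises, with Slc7a5 at 2.22, and 2 falls, with Vldlr at -2.61, among 22 (10 and 2 adjusted over the list alone). The ATF4 list gave adjusted p = 0.015, and adjusted p = 0.212 with an estimated correlation. Cholesterol synthesis genes had 8 rises and 1 fall among 18 (9 and 1 adjusted over the list alone), with Sqle at 1.89 and Msmo1 at 1.28. The cholesterol list gave adjusted p = 0.000325, and adjusted p = 0.128 with an estimated correlation. Fetal and wall-stress genes rose in 10 of 14 and fell in 1 (10 and 1 adjusted over the list alone). Mybpc2, also a fast skeletal muscle gene, was at 3.32, Xirp1 at 3.11 and Uchl1 at 2.19. The fetal gene list gave adjusted p = 0.000182, and adjusted p = 0.28 with an estimated correlation. Beside them, 6 of 12 atrial cardiomyocyte markers were higher and 2 lower (6 and 2 adjusted over the list alone), with Myl7 at 2.31 and Sln at 2.09, though the list did not pass (adjusted p = 0.497). Both genes spread widely among the controls, Myl7 from 6.99 to 11.4 and Sln from 7.15 to 10.6.

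Calcium handling and ion channel genes were lower at day 3, 14 of 23 down and 1 up (15 and 2 adjusted over the list alone), with the sodium-calcium exchanger gene Slc8a1 at -2.74 and Cacnb2 at -2.67. The calcium handling list gave adjusted p = 9.86e-08, and adjusted p = 0.168 with an estimated correlation. Lower too were lists of mitochondrial metabolism. Mitochondrial biogenesis regulators had 10 falls and 1 rise among 15 (11 and 1 adjusted over the list alone), including Ppargc1b at -2.05 and Tfam at -0.97. The biogenesis list gave adjusted p = 4.86e-05, and adjusted p = 0.212 with an estimated correlation. Oxidative phosphorylation genes fell in 29 of 74 (30 adjusted over the list alone), with adjusted p = 2.14e-07, and adjusted p = 0.403 with an estimated correlation. Fatty acid oxidation genes fell in 12 of 27 and rose in 1 (12 and 1 adjusted over the list alone), with adjusted p = 0.000182, and adjusted p = 0.403 with an estimated correlation. Pyruvate dehydrogenase and TCA cycle genes fell in 11 of 19 (12 adjusted over the list alone), with Mdh1 at -1.62. The TCA cycle list gave adjusted p = 0.000329, and adjusted p = 0.433 with an estimated correlation. Sarcomere genes of the adult ventricle had 7 falls and 2 rises among 21 (7 and 2 adjusted over the list alone; Pdlim5 -2.11, Des 0.89). The sarcomere list gave adjusted p = 0.0238, and adjusted p = 0.403 with an estimated correlation. Of 22 macrophage and monocyte markers, 7 were higher (8 adjusted over the list alone), led by Gpnmb and the galectin gene Lgals3 (3.39), with a median of 0.27. The macrophage list gave adjusted p = 0.00878, and adjusted p = 0.616 with an estimated correlation. Over the 10 pairs of controls the median was above 0 for 9 and ran from -0.16 (controls 4 and 5) to 0.82 (controls 2 and 3), with 3 to 13 members called higher.

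The size of the largest rises at day 3 depended on single arrays: without day 3 replicate 1, Hspa1a, Timp1 and Tnc rose 47.3-fold, 45.2-fold and 30.3-fold, and without day 3 replicate 2, 19.4-fold, 13.6-fold and 8.53-fold. Nppa was not called without control 1 (adjusted p = 0.102), control 3 (0.109), control 4 (0.0956), control 5 (0.072), or day 3 replicate 1 (0.0952), 2 (0.156) or 3 (0.0727). It was not called either without background correction (0.0757), with an offset of 16 (0.0688), trended, robust variances (0.133), array weights (0.0806) or controls 1 to 3 alone (0.156). Col1a1 was called without control 2 (0.0428), control 5 (0.045) or day 3 replicate 1 (0.0325) and with the replicate number as a block (0.0376), and Acta1 was not called with trended, robust variances (0.0553). Without day 3 replicate 2 the sarcomere (0.0638), ATF4 (0.0722) and macrophage (0.219) lists were not called, nor was the sarcomere list with a 50th percentile filter (0.0769). Tnc rose 9.25-fold with no background correction and 22.5-fold with an offset of 16.

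**Figure D3:**
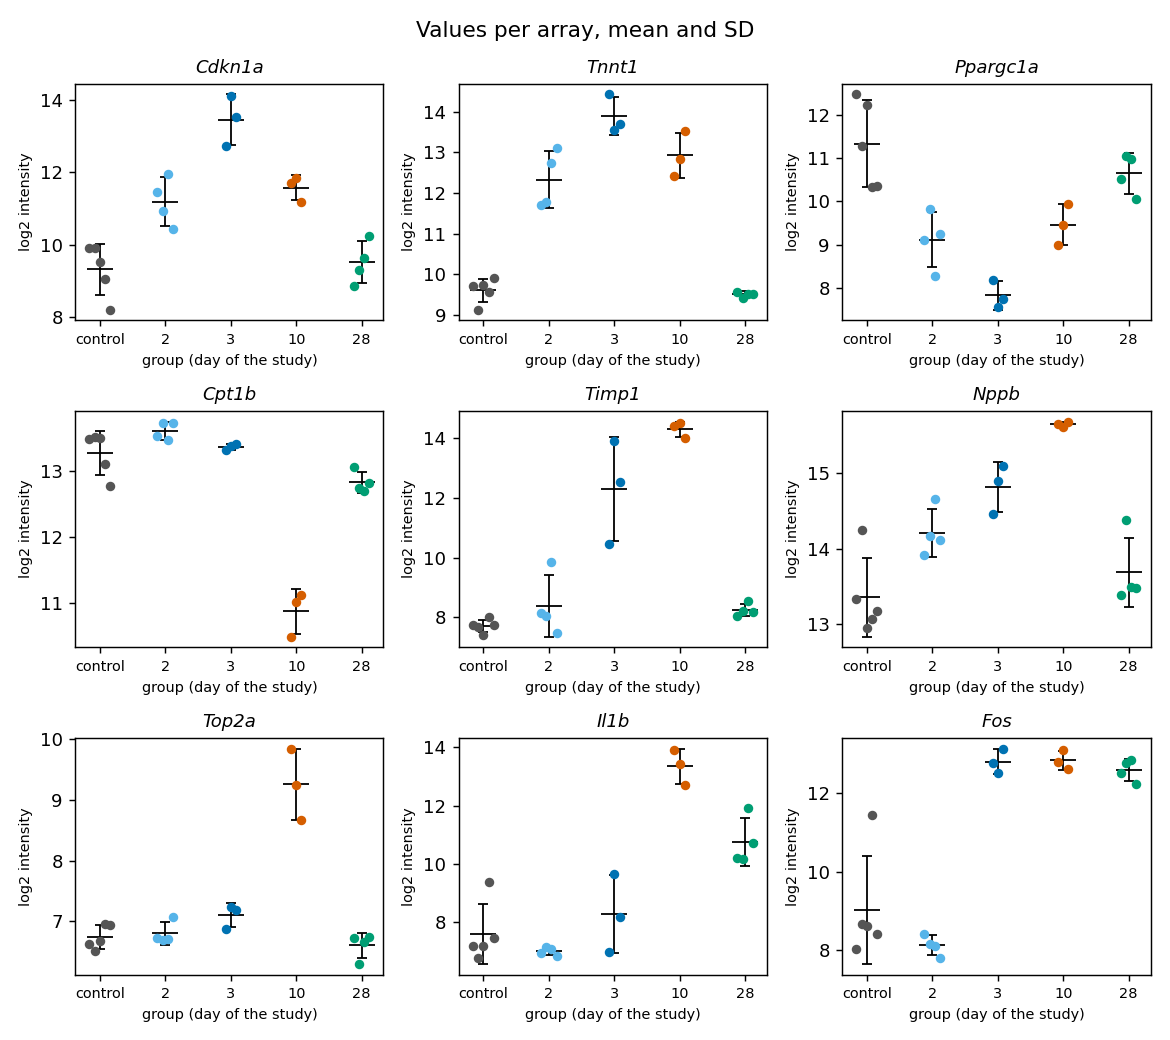
Log2 intensity of 9 genes on each array (points), with the group mean and SD (bars), in control and at days 2, 3, 10 and 28. Cdkn1a and Tnnt1 were highest and Ppargc1a lowest at day 3, Cpt1b was lowest and Timp1, Nppb, Top2a and Il1b highest at day 10, and Fos was still high at day 28 (12.60 ± 0.28) with control replicate 4 (11.5) above the other controls.

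Directly against day 2, day 3 had 3612 called probes (1685 up, 1927 down). The rises of Fos (log2 4.67 ± 0.46 SE, adjusted p = 2.97e-07), Hspa1a (4.49 ± 0.61 SE, adjusted p = 1.22e-05) and Timp1 (3.90 ± 0.50 SE, adjusted p = 6.36e-06) and the falls of Pln (-2.57), Grb14 (-2.45) and Yipf7 (-2.24) were the largest. Immediate early genes had 16 rises among 21 (18 adjusted over the list alone), with adjusted p = 7.7e-14, and adjusted p = 0.0643 with an estimated correlation. Cytokine and NF-kB target genes had 13 rises among 28 (15 adjusted over the list alone), with adjusted p = 5.65e-08, and adjusted p = 0.257 with an estimated correlation. Of 31 lists 13 were called, and 0 with an estimated correlation. The count was 2241 without day 3 replicate 2 and 5669 with array weights. Hspa1a and Timp1 stood at 34.3-fold and 28.4-fold without day 3 replicate 1 and at 14.1-fold and 8.57-fold without replicate 2.

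At day 10, the time the series gives for the deepest dysfunction, genes of matrix remodelling, macrophages and the cell cycle were higher than in control and genes of fatty acid and mitochondrial metabolism were lower. Timp1 (probe ILMN_3103896) rose 94.6-fold, from 7.72 ± 0.21 (SD, n = 5) to 14.28 ± 0.26 (SD, n = 3). The interleukin gene Il1b rose 53.3-fold (log2 5.74 ± 0.50 SE, adjusted p = 3.36e-09) and Lgals3 24.1-fold (4.59 ± 0.32 SE, adjusted p = 1.38e-10). Every one of the 27 measured fatty acid oxidation genes fell, and Ces1d, a lipid-hydrolysing carboxylesterase gene, fell by 4.23 ± 0.25 SE (adjusted p = 2.47e-11). The alpha myosin heavy chain gene Myh6 fell by 1.37 ± 0.16 SE (adjusted p = 1.82e-07), and Nppb rose 4.86-fold, to 15.64 ± 0.03 (SD, n = 3), close to the highest log2 value of the table (15.8).

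Other large rises at day 10 were in Arg1, arginase 1 (log2 5.23), Chil3, a chitinase-like gene of macrophages and neutrophils (5.14), Tnc (5.09, 4 of 5 probes), the collagen cross-linking enzyme gene Lox (4.37) and Ms4a6d (4.15). Arg1, Chil3 and Tnc rose from control values below the median of all probes. Other large falls were in Fndc5, the precursor of irisin (-3.40), Perm1, a regulator of mitochondrial genes in muscle (-3.11), Txlnb (-3.05, 1 of 2 probes), the muscle gene Ky (-3.05), Lynx1 (-3.05), Lgals4 (-3.04) and the tubulin-modifying gene Ttll1 (-3.02, 2 of 3 probes). The fixed genes Nppa (1.77), Cdkn1a (2.26) and Col1a1, a chain of type I collagen (1.97), rose, while Ppargc1a (-1.87), Atp2a2, the cardiac calcium pump gene (-0.76), and Myh7 (-1.01, adjusted p = 0.0427) fell. Acta1 (-0.67) and Esr1 (-0.07) did not pass. Of the 24 named genes called at day 10, 23 lay beyond every control array in 3 of 3 arrays, and Myh7 did so in 2 of 3 and lay beyond the control mean in 3 of 3.

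The fatty acid oxidation list had 27 falls among 27 (27 adjusted over the list alone), median -1.35, with Mlycd at -2.47, the carnitine palmitoyltransferase genes Cpt1b at -2.40 and Cpt2 at -2.27, and Decr1 at -2.11. The fatty acid list gave adjusted p = 2.17e-17, and adjusted p = 0.0917 with an estimated correlation. Oxidative phosphorylation genes had 53 falls and 1 rise among 74 (58 and 1 adjusted over the list alone), with Ndufb10 at -2.02. The oxidative phosphorylation list gave adjusted p = 8.97e-15, and adjusted p = 0.115 with an estimated correlation. Pyruvate dehydrogenase and TCA cycle genes had 17 falls and 1 rise among 19 (17 and 1 adjusted over the list alone), with Pdk2 at -2.47 and Dlat at -2.37. The TCA cycle list gave adjusted p = 1.1e-10, and adjusted p = 0.105 with an estimated correlation. Mitochondrial biogenesis regulators had 13 falls and 1 rise among 15 (13 and 1 adjusted over the list alone), with Esrrb at -1.83. The biogenesis list gave adjusted p = 1.76e-06, and adjusted p = 0.102 with an estimated correlation. Calcium handling and ion channel genes fell in 18 of 23 (19 adjusted over the list alone), with Hrc at -2.72 and Kcnip2 at -2.10. The calcium handling list gave adjusted p = 3.72e-07, and adjusted p = 0.105 with an estimated correlation. Sarcomere genes had 10 falls and 3 rises among 21 (10 and 4 adjusted over the list alone; Tnni3 -1.48, Tpm1 1.74). The sarcomere list gave adjusted p = 0.0491, and adjusted p = 0.286 with an estimated correlation. Glucose uptake and glycolysis genes, among which the glucose transporter gene Slc2a4 (-2.78) and Pfkm (-2.19) fell, had 9 falls and 4 rises among 19 (9 and 4 adjusted over the list alone) and were not called as a list (adjusted p = 0.0748).

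Cell cycle genes rose at day 10 in 26 of 31, with 1 fall (28 and 1 adjusted over the list alone), among them Cdk1 at 2.99, Tyms at 2.62 and Top2a at 2.52. The cell cycle list gave adjusted p = 3.84e-16, and adjusted p = 0.0917 with an estimated correlation. Cytokine and NF-kB target genes rose in 23 of 28 (24 up and 1 down adjusted over the list alone), with Lcn2 at 3.93 and Tnf at 3.71. The cytokine list gave adjusted p = 5.74e-11, and adjusted p = 0.102 with an estimated correlation. Extracellular matrix genes had 23 rises and 1 fall among 38 (23 and 1 adjusted over the list alone). The matrix list gave adjusted p = 1.96e-08, and adjusted p = 0.115 with an estimated correlation. The unfolded protein response had 11 rises and 1 fall among 17 (11 and 1 adjusted over the list alone; Sec61b 1.36, Xbp1 1.15, Herpud1 -1.84). The unfolded protein list gave adjusted p = 0.0032, and adjusted p = 0.0958 with an estimated correlation. Cholesterol synthesis genes had 10 rises and 1 fall among 18 (12 and 2 adjusted over the list alone; Sqle 2.58, Msmo1 2.15). The cholesterol list gave adjusted p = 6.05e-05, and adjusted p = 0.0917 with an estimated correlation. Fetal and wall-stress genes had 8 rises and 1 fall among 14 (8 and 1 adjusted over the list alone), with Fhl1 at 2.29. The fetal gene list gave adjusted p = 0.000384, and adjusted p = 0.168 with an estimated correlation. Immediate early genes had 11 rises and 2 falls among 21 (12 and 2 adjusted over the list alone), with Fos at 3.80. The immediate early list gave adjusted p = 0.00171, and adjusted p = 0.24 with an estimated correlation. Interferon response genes had 15 rises and 1 fall among 32 (15 and 1 adjusted over the list alone), with Ifitm3 at 1.58. The interferon list gave adjusted p = 0.00286, and adjusted p = 0.431 with an estimated correlation. Clock genes had 7 falls and 3 rises among 14 (8 and 3 adjusted over the list alone; Dbp -2.53, Nr1d2 -1.87). The clock list gave adjusted p = 0.0491, and adjusted p = 0.286 with an estimated correlation.

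Markers of cell types moved in different directions at day 10. Macrophage and monocyte markers rose in 21 of 22 (21 adjusted over the list alone), median 2.32, with Fcgr3 at 2.73, Trem2 at 2.68 and Mrc1 at 2.20. The macrophage list gave adjusted p = 3.64e-16, and adjusted p = 0.0958 with an estimated correlation. Neutrophil markers rose in 7 of 12 (7 adjusted over the list alone; Csf3r 1.83, Cxcr2 1.40). The neutrophil list gave adjusted p = 0.00126, and adjusted p = 0.118 with an estimated correlation. Endothelial markers fell in 9 of 17 (9 adjusted over the list alone), with Aqp1 at -1.70 and Flt1 at -1.14. The endothelial list gave adjusted p = 0.000734, and adjusted p = 0.102 with an estimated correlation. Smooth muscle and pericyte markers had 8 falls and 2 rises among 14 (9 and 2 adjusted over the list alone), with Abcc9 at -2.01. The smooth muscle list gave adjusted p = 0.0117, and adjusted p = 0.187 with an estimated correlation. Atrial markers fell in 5 of 12 (5 adjusted over the list alone), with Kcnk3 at -2.05. The atrial list gave adjusted p = 0.0196, and adjusted p = 0.115 with an estimated correlation. Fibroblast markers had 4 rises, with Mfap5 at 2.50, and 4 falls, with Scara5 at -2.83, among 15 (4 and 4 adjusted over the list alone; adjusted p = 0.961).

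Calls near the edge at day 10 changed with single arrays and with the processing. Myh7 was not called without control 1 (adjusted p = 0.0653), control 2 (0.117), control 3 (0.0538), or day 10 replicate 1 (0.179) or 2 (0.148), and Acta1 was called, lower, without day 10 replicate 3 (0.0435). Myh7 was not called either without background correction (0.0816), with an offset of 16 (0.0507), with the 2 groups fitted alone (0.0868) or with trended, robust variances (0.119). Sarcomere genes were not called without control 2 (0.0722) or 3 (0.057) or day 10 replicate 1 (0.0622) or 2 (0.0638), nor without background correction (0.057), with an offset of 16 (0.0515), a 50th percentile filter (0.0994) or the 2 groups fitted alone (0.0704). Clock genes were not called without control 1 (0.0687), 2 (0.0733) or 3 (0.0798) or day 10 replicate 1 (0.0622) or 3 (0.085), nor without background correction (0.0656), with an offset of 16 (0.0515) or a 50th percentile filter (0.0873). Interferon genes were not called without day 10 replicate 1 (0.0941), and glycolysis genes were called without control 5 (0.0443) and with controls 1 to 3 alone (0.0425). Folds of genes that are dim in 1 group moved with the background setting, from 18.9 without correction to 68.4 with an offset of 16 for Arg1, 19.6 to 55.2 for Chil3, 19.4 to 51.5 for Tnc, and 5.28 to 11.5 for the fall of Ky.

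**Figure D4:**
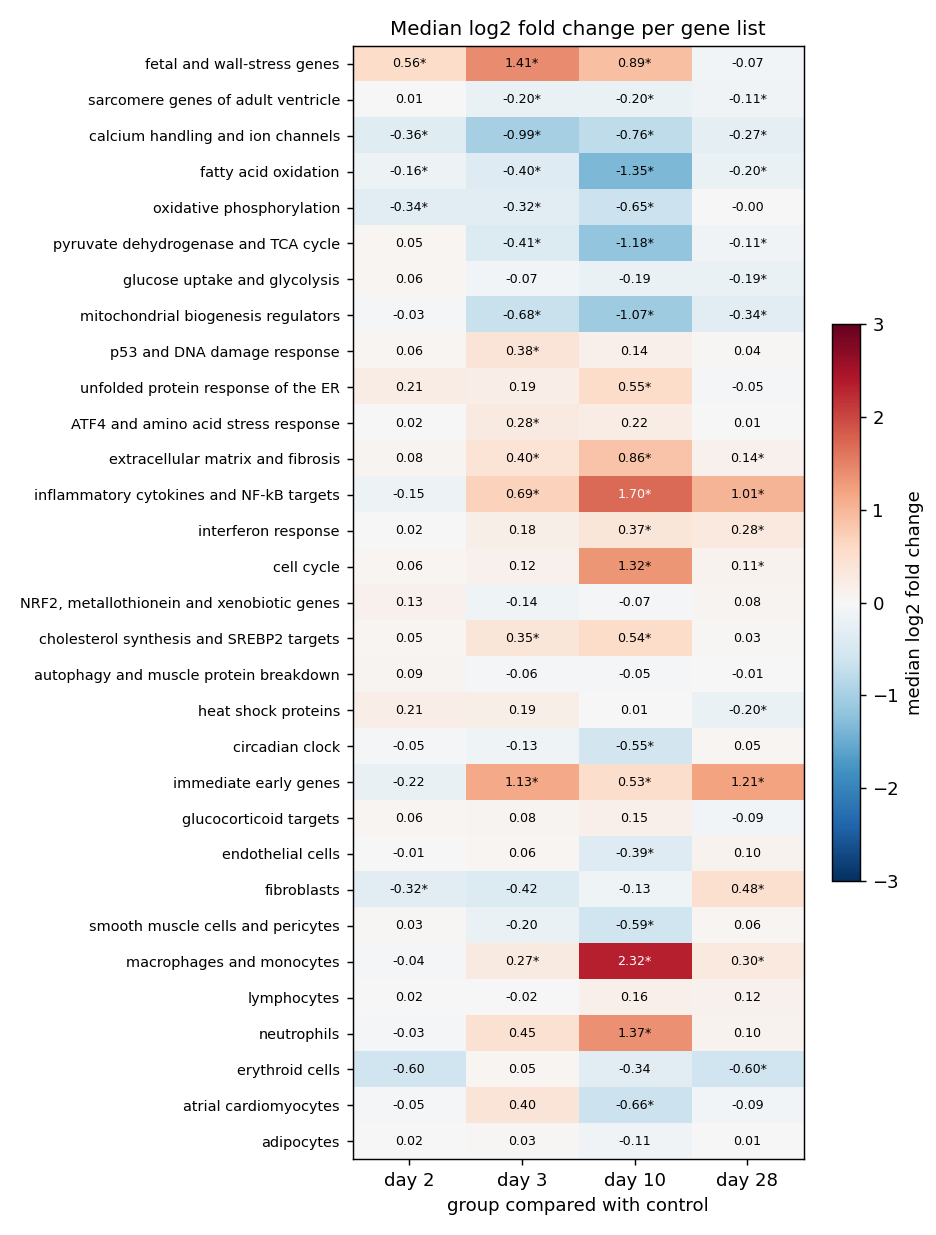
Median log2 fold change against control of the 31 gene lists (rows) at days 2, 3, 10 and 28 (columns), with an asterisk where the list test at the preset correlation gave an adjusted p under 0.05. The fatty acid oxidation (-1.35), TCA cycle (-1.18), mitochondrial biogenesis (-1.07) and oxidative phosphorylation (-0.65) lists were lowest at day 10, macrophage markers were highest at day 10 (2.32), and immediate early genes were high at day 3 (1.13) and day 28 (1.21).

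Directly against day 3, day 10 had 6053 called probes (3076 up, 2977 down). The largest rises were in Il1b (log2 5.07 ± 0.56 SE, adjusted p = 2.15e-07), Arg1 (4.42) and the cystatin gene Stfa1 (4.03), and the largest falls in the atrial light chain gene Myl7 (-4.24), Hspa1a (-4.21) and sarcolipin, Sln (-4.16). Fatty acid oxidation genes fell in 23 of 27 (23 adjusted over the list alone), with adjusted p = 1.37e-11, and adjusted p = 0.165 with an estimated correlation. Cell cycle genes had 25 rises and 1 fall among 31 (26 and 1 adjusted over the list alone), with adjusted p = 1.38e-13, and adjusted p = 0.165 with an estimated correlation. Macrophage markers had 19 rises and 1 fall among 22 (20 and 1 adjusted over the list alone), with adjusted p = 1.37e-11, and adjusted p = 0.198 with an estimated correlation. Atrial markers fell in 6 of 12 (6 adjusted over the list alone), with adjusted p = 0.00661, and adjusted p = 0.165 with an estimated correlation. Myl7 and Sln also spread widely within other groups. Myl7 ran from 6.99 to 11.4 in control and 6.94 to 10.7 at day 2, and Sln from 7.15 to 10.6 and 6.81 to 9.46. Their falls can therefore not be set down to the time alone. Of 31 lists 13 were called, and 0 with an estimated correlation. Il1b stood at 21.5-fold without day 3 replicate 1 and 54.3-fold without replicate 2, and Arg1 at 42.3-fold without replicate 2. Hspa1a stood at 28.3-fold lower without replicate 1 and 11.6-fold lower without replicate 2, and Sln at 29.1-fold lower without replicate 3. Folds also moved with the background setting, from 12.5 without correction to 34.9 with an offset of 16 for Arg1, 8.24 to 33.2 for Stfa1 and 10.7 to 26.2 for the fall of Sln. Stfa1 at day 3 and Sln at day 10 lay below the median of all probes.

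At day 28 far fewer probes were called than at day 10, and the 8 genes with the largest rises were immediate early and inflammatory genes. The chemokine gene Cxcl1 (probe ILMN_2763245) was 32.9-fold higher, at 13.49 ± 0.66 (SD, n = 4) against 8.45 ± 1.52 (SD, n = 5) in control. Fos was 11.8-fold higher (log2 3.56 ± 0.41 SE, adjusted p = 1.51e-05) and Egr1 10.9-fold (3.45 ± 0.41 SE, adjusted p = 2.46e-05), both transcription factor genes of the immediate early class. Of the fixed genes none passed: Nppa was at 0.13, Nppb 0.33, Myh6 -0.27 (1 of its 2 probes called lower), Myh7 -0.63, Acta1 -0.36, Atp2a2 -0.00, Ppargc1a -0.68, Cdkn1a 0.20, Col1a1 -0.26 and Esr1 0.18.

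Large rises at day 28 were also those of Egr2 (3.70), Fosb (3.48), Junb (3.45), Il1b (3.14) and Nfkbiz, an inducible regulator of NF-kB (3.08). Falls were small. The largest were in the rhomboid protease gene Rhbdl2 (-1.23), the acyl-CoA thioesterase gene Acot1 (-1.07), the kinase gene Wnk2 (-1.01), Ppargc1b, a relative of Ppargc1a (-1.00), Ccdc141 (-1.00, to a value below the median of all probes), the lipid droplet gene Plin4 (-0.94), Tmem82 (-0.93) and Lrg1 (-0.90). All 16 lay beyond every control array in 4 of 4 arrays. The named falls except Acot1 were already lower in controls 4 and 5 than in controls 1 to 3. Rhbdl2 lay at 8.77 and 9.07 in controls 4 and 5, 10.2 to 10.4 in controls 1 to 3 and 8.37 to 8.74 at day 28.

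Immediate early genes were higher at day 28 in 15 of 21 (16 adjusted over the list alone), median 1.21, with Ccn1 at 2.62 and Zfp36 at 2.35. The immediate early list gave adjusted p = 4.43e-28, and adjusted p = 0.00298 with an estimated correlation. Cytokine and NF-kB target genes were higher in 13 of 28 (17 adjusted over the list alone), with Vcam1 at 1.70. The cytokine list gave adjusted p = 6.51e-18, and adjusted p = 0.0894 with an estimated correlation. Extracellular matrix genes had 6 rises among 38 (9 up and 2 down adjusted over the list alone), with Thbs1 at 1.62 and Ccn2 at 1.22. The matrix list gave adjusted p = 0.000886, and adjusted p = 0.492 with an estimated correlation. Fibroblast markers had 3 rises among 15 (7 adjusted over the list alone), with Lum at 1.13. The fibroblast list gave adjusted p = 0.000244, and adjusted p = 0.264 with an estimated correlation. Macrophage markers (Cd14 2.04) and interferon genes (Irf1 1.04) had 1 called member each, of 22 and 32, and 1 each adjusted over the list alone (adjusted p = 0.00179 and 0.00139, and adjusted p = 0.578 for both with an estimated correlation). Both medians were above 0 for 9 of the 10 pairs of controls. Against controls 4 and 5 they were -0.19 and -0.04, and against controls 2 and 3 they were 0.75 and 0.45. Fatty acid oxidation, calcium handling, mitochondrial biogenesis and glycolysis genes were lower as lists with 1 called member each. Their medians were below 0 for all 10 pairs of controls, but their size followed which controls were used. Calcium handling ran from -0.53 (controls 1 and 3) to -0.05 (controls 4 and 5) and biogenesis from -0.49 (controls 2 and 3) to -0.08 (controls 4 and 5). Glycolysis ran from -0.28 (controls 1 and 3) to -0.06 (controls 4 and 5) and fatty acid oxidation from -0.29 to -0.10. Fatty acid oxidation had a median of -0.20 with Slc27a1 called at -0.78 (7 down adjusted over the list alone), and adjusted p = 5.33e-05, or adjusted p = 0.366 with an estimated correlation. Calcium handling had a median of -0.27 with Kcnv2 at -0.60 (6 down adjusted over the list alone), and adjusted p = 2.96e-05, or adjusted p = 0.264 with an estimated correlation. Mitochondrial biogenesis had a median of -0.34 with Ppargc1b called (1 down adjusted over the list alone), and adjusted p = 0.000205, or adjusted p = 0.264 with an estimated correlation. Glycolysis had a median of -0.19 with Pfkl at -0.55 (2 down adjusted over the list alone), and adjusted p = 0.00181, or adjusted p = 0.264 with an estimated correlation.

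The day 28 count depended on single arrays: it was 130 without control 1, 182 without control 2, 139 without control 3, 679 without control 4, 772 without control 5, and 153, 105 and 137 without day 28 replicates 2, 3 and 4. It was 1874 with controls 1 to 3 alone, 336 of which were among the 347. Without control 4, Cxcl1, Egr2, Fos and Egr1 were 52.5-fold, 19.7-fold, 17.9-fold and 16.9-fold higher, and with controls 1 to 3 alone Ppargc1a (-1.35) and Myh7 (-1.15) were called lower. Of the 8 named falls, Acot1 and Lrg1 were called whichever array was left out. Without 1 array the others lost their call: Rhbdl2 (controls 1, 2 or 3 or any day 28 array, adjusted p = 0.102 to 0.153), Ppargc1b (the same 7 arrays, 0.0644 to 0.129), Plin4 (the same, 0.0556 to 0.0779), Ccdc141 (the same except day 28 replicate 1, 0.0557 to 0.0776), Tmem82 (control 1 or 3, day 28 replicate 2 or 3, 0.0534 to 0.08) and Wnk2 (day 28 replicate 2, 0.0512). Rhbdl2 was not called either without background correction (0.0783), with an offset of 16 (0.0772), the 2 groups fitted alone (0.0515) or trended, robust variances (0.128), nor Ppargc1b with an offset of 16 (0.0756) or trended, robust variances (0.0736).

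Between day 10 and day 28 fatty acid oxidation and other mitochondrial genes rose and macrophage, cell cycle and most of the called matrix genes fell, with 5791 probes called (2893 up, 2898 down). Inmt, a methyltransferase gene (probe ILMN_2803249), was 32.5-fold higher at day 28, at 11.70 ± 0.97 (SD, n = 4) against 6.68 ± 0.10 (SD, n = 3), a value below the median of all probes. Ces1d was 16.6-fold higher (log2 4.05 ± 0.27 SE, adjusted p = 1.56e-10). Timp1 fell by 6.03 ± 0.50 SE (adjusted p = 3.75e-09), to 8.25 ± 0.21 (SD, n = 4), and Col1a1 fell by 2.24 ± 0.25 SE (adjusted p = 2.69e-07).

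The other large rises from day 10 to day 28 were in the matrix gene Fbln1 (log2 3.05), the clock output gene Dbp (2.96), Ttll1 (2.94, 2 of 3 probes), Fndc5 (2.88), Txlnb (2.87, 1 of 2 probes) and Art1 (2.81). The other large falls were in Arg1 (-5.54), Chil3 (-5.13), Tnc (-5.05, 4 of 5 probes), Lcn2 (-4.36), Lgals3 (-4.24), Ms4a6d (-3.98) and Lox (-3.83). Myh6 (1.10), Atp2a2 (0.75) and Ppargc1a (1.19, adjusted p = 0.0328) rose and Nppa (-1.64), Nppb (-1.95) and Cdkn1a (-2.06) fell, whereas Myh7 (0.39), Acta1 (0.30) and Esr1 (0.25) did not pass. All 23 named genes called lay beyond every day 10 array in 4 of 4 arrays.

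Of the lists called between day 10 and day 28, 5 were also called with an estimated correlation, each at adjusted p = 0.0452. Fatty acid oxidation genes rose in 25 of 27 (26 adjusted over the list alone; Mlycd 1.98, Cpt1b 1.96; adjusted p = 4.91e-17) and endothelial markers in 11 of 17 (11 adjusted over the list alone; Aqp1 1.82; adjusted p = 1.25e-05). Cell cycle genes fell in 26 of 31 with 1 rise (26 and 1 adjusted over the list alone; Top2a -2.66, Cdk1 -2.58; adjusted p = 4.91e-17). Cholesterol synthesis genes fell in 11 of 18 (12 adjusted over the list alone; Sqle -2.33; adjusted p = 1.25e-05), and unfolded protein response genes in 11 of 17 with 2 rises (11 and 2 adjusted over the list alone; Pdia4 -1.36, Herpud1 1.67; adjusted p = 0.000774). Macrophage markers fell in 21 of 22 (21 adjusted over the list alone), with adjusted p = 1.73e-16, and adjusted p = 0.0795 with an estimated correlation. Oxidative phosphorylation genes had 57 rises and 1 fall among 74 (65 and 1 adjusted over the list alone), with adjusted p = 4.91e-17, and adjusted p = 0.114 with an estimated correlation. Extracellular matrix genes had 22 falls and 4 rises among 38 (23 and 5 adjusted over the list alone), with adjusted p = 2.22e-06, and adjusted p = 0.183 with an estimated correlation. Immediate early genes had 7 rises and 2 falls among 21 (7 and 2 adjusted over the list alone), with Klf2 at 1.91 and Klf4 at 1.62. The immediate early list gave adjusted p = 0.0267, and adjusted p = 0.417 with an estimated correlation. Ppargc1a was not called without day 10 replicate 1 (adjusted p = 0.16) or 2 (0.0822) or day 28 replicate 2 (0.0903) or 3 (0.0839), without background correction (0.0571) or with trended, robust variances (0.104). Immediate early genes were not called without day 10 replicate 3 (0.0638) or day 28 replicate 3 (0.0532), or with a 50th percentile filter (0.0581). Folds moved with the background setting, from 18.9 without correction to 48.1 with an offset of 16 for Inmt, and for the falls of Arg1 from 21.1 to 108, of Chil3 from 19.5 to 55 and of Tnc from 19.2 to 49.7. Arg1, Chil3 and Tnc lay below the median of all probes at day 28.

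Of the 6894 probes called at day 10 against control, 5003 (72.6%) were called in the opposite direction between day 10 and day 28, 2561 of the 3409 that had risen (75.1%) and 2442 of the 3485 that had fallen (70.1%). Of the 2134 that had changed at least 2-fold, 2012 (94.3%) were called back. At day 28, 243 of the 6894 were still called against control in the same direction and 19 in the opposite direction, and 3 had moved further away. These classes overlap: 91 of the 243, and all 19 of the opposite ones, were also called back, and the 3 are among the 243. Called in neither comparison were 1739. The median ratio of the day 28 to the day 10 log2 change was 0.167, and 85 probes were called at day 28 and not at day 10 (67 up, 18 down). Probes chosen on the day 10 arrays fall back in part by chance. Independent lists would share 37.9 rises and 24.1 falls between day 10 and day 28, against the 133 and 110 found, and with the controls split the shared calls were 22 to 712 over 20 splits. The 243 became 96, 120 and 98 without controls 1, 2 and 3, 466 and 567 without controls 4 and 5, 112, 75 and 100 without day 28 replicates 2, 3 and 4, and 1338 with controls 1 to 3 alone.

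Calls were shared between neighbouring times. Of the 1279 day 2 calls, 491 were called up and 540 down at both day 2 and day 3, and 10 in opposite directions, where independent lists would share 91.9 and 89.6. Day 3 and day 10 shared 1181 rises and 1549 falls with 426 opposite, where independent lists would share 479 and 499. When the controls were split, so that each time was compared with different controls, the shared calls were 276 to 826 for days 2 and 3 and 1813 to 2241 for days 3 and 10 over 20 splits. The day 2 and day 3 overlap of 1031 was 620 without day 2 replicate 3 and 643 with controls 1 to 3 alone.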

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

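The tests of the control pairs and of each control alone, of the clock genes at day 28, of the gap between troponins and other skeletal muscle transcripts and of cell type markers at day 10 were chosen only after the results they concern were seen.

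In each group of 4 or 5 arrays, 133 values of named genes were tested for an array far from the others, and 16 stood apart, where chance gives about 6.65 at 1 in 20. In control replicate 4, 9 genes lay above the other controls on the log2 scale: Fos (11.5, the others 8.03 to 8.67), Egr1 (13.6, the others 10.1 to 10.7), Egr2 (9.96), Junb (10.7), Cxcl1 (11.1), Nfkbiz (9.41), Il1b (9.40), Tnc (7.09) and Arg1 (6.66). In control replicate 2, Nlrc3 (8.84, the others 7.06 to 7.42) and Nppa (15.2, the others 13.4 to 13.8) were high. Atp2a2 was low in day 2 replicate 3 (15.5, the others 15.8). Among the day 28 arrays, replicate 2 was high for Nppb (14.4) and Myh7 (8.56), replicate 1 was low for Fbln1 (11.1), and replicate 4 was low for Dbp (12.4).

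Groups of different times differed by a direct test of the 2 times: 5791 probes between day 28 and day 10, 3612 between day 3 and day 2, and 6053 between day 10 and day 3.

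Immediate early genes were higher at day 28 than in control, with a list median of 1.21. To test a difference among the controls as the source of the whole rise, day 28 was set beside each control alone, and it matched none. The list median of the day 28 mean over a single control was lowest for control 4, at 0.72 (interval over the members 0.48 to 1.30). The interval lay above 0 for each of the 5. These intervals are over genes of the same arrays and do not measure the spread between mice. They speak for these 5 controls alone, so a difference among controls is not excluded as the source of the whole rise. How much of the rise such a difference adds stays open, since the median over the 10 pairs of controls ranged from 0.85 (controls 1 and 4, interval 0.60 to 2.07) to 1.55. A different time of day of collection is not excluded either: the median absolute change of 14 clock genes at day 28 was 0.22 (0.08 to 0.43). That value uses the mean of all 5 controls, which can hide a difference from some of them. Arntl lay at 6.79 to 6.86 at day 28, beside controls 4 and 5 (6.74 to 6.96) and below controls 1 to 3 (7.69 to 8.26). Per2 overlapped between them, at 9.65 to 10.4, 9.62 to 9.99 and 9.87 to 10.5. Handling of the tissue, on which the labels say nothing, was not tested, and the time after tamoxifen, the biological difference that the design names, stays open. For the rises of the same list at day 3 and day 10, time of day and handling were not tested and stay open too.

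The skeletal troponins Tnnt1, Tnni2 and Tnnt3 rose from day 2, and at day 3 Tnnt3 stood at 3.62 and Tnni2 at 3.32 on the log2 scale. Skeletal muscle tissue in the samples would bring its other abundant transcripts too. The test of such tissue as the source of the whole rise of Tnnt3 and Tnni2 compared their changes. Tnni2 exceeded the median of the 8 abundant transcripts that start no higher than Tnni2 by 2.79 (2.12 to 3.82, from the interval over the members and 2 SE of Tnni2). Those 8 were Pvalb (7.04 in control, 8.33 at day 3), Mylpf (7.77 and 8.51), Casq1 (6.41 and 7.06), Atp2a1 (6.73 and 7.26) and Tnnc2 (6.44 and 6.97), called higher, and Myh1 (6.50 and 6.46), Mybpc1 (6.52 and 6.43) and Actn3 (6.90 and 7.07), not called. In control Casq1, Atp2a1, Tnnc2, Myh1 and Mybpc1 lay below the median of all probes, where a value cannot be told from background. Their small changes may understate skeletal muscle RNA, so the gap cannot exclude it as the whole source. Pvalb (1.29), Mylpf (0.74) and Actn3 (0.17), which lay above that median, also rose less than Tnni2. The others of the 11 measured, Ckm (13.9 and 14.1), Eno3 (14.5 and 15.0) and Myl1 (12.6 and 12.4), start high and had no call. Mybpc2, a fast skeletal muscle gene placed in the fetal and wall-stress list instead, rose as much as Tnni2 at day 3 (3.32). Skeletal muscle tissue as the source of part of the rise cannot be told apart from a change in the heart, since the median of the 11 was 0.53 (interval -0.05 to 0.66) and 5 of them rose. For Tnnt1, a slow muscle gene, the list holds Mybpc1, of the slow type, which lay below the median of all probes in control and at day 3. The list therefore cannot decide on Tnnt1. The time after tamoxifen stays open as a biological explanation.

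The fall of fatty acid oxidation genes at day 10 (27 of 27, median -1.35) was weighed against a lower share of cardiomyocyte RNA and against the normalization. A loss of cardiomyocyte RNA alone would raise the markers of all other cell types alike, which was not seen. The macrophage median exceeded the endothelial median by 2.71 (interval 2.32 to 3.42), and endothelial markers fell. An influx of macrophages would also lower the cardiomyocyte share, with macrophage markers up (median 2.32) and endothelial markers down (-0.39). The test cannot decide on that, so a share lowered in this way stays open. Random lists of the same intensity had a median of -0.17 (range -0.71 to 0.57 over 10000 lists), and 0 reached -1.35, which argues against a shift that the quantile normalization gives to all genes of that intensity. A change in fatty acid oxidation expression within cardiomyocytes stays a hypothesis, found and tested on the same arrays. It was not told apart from a share lowered by an influx of other cells, and tamoxifen, Cre and time stay confounded.

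Other splits of the same arrays into groups of the same sizes were counted, the real split included. For day 2 and day 28 against control these were a random draw, 100 splits with the real one. As many calls were reached in 1 of 100 splits at day 2 (1279 calls, highest other 525) and 1 of 56 at day 3 (5470, highest other 1183). It was 1 of 56 at day 10 (6894, highest other 3606) and 1 of 35 for day 28 against day 10 (5791, highest other 2713). For day 3 against day 2 it was 1 of 35 (3612). The highest other there, 2980, differed from the real split by day 2 replicate 3 alone. These shares are the least that so many splits allow and were not adjusted over the comparisons. Chance is thus unlikely for these counts but not excluded. At day 28 the share was 2 of 100 (347 calls), and the other split was higher, at 765. It set controls 1 to 4 against control 5 and the day 28 arrays, so it sets control 5 apart and does not bear on control 4. The rank correlation of controls 4 and 5 (0.931) lay within that of these 2 with controls 1 to 3 (0.921 to 0.935). Among controls 1 to 3 it was 0.945 to 0.946. The share of 2 in 100 is under 0.05, but a split that cuts across the groups gave more calls than the real one. Chance is therefore not called excluded for the 347. The labels give no date, slide or batch, so that a set of collection or processing shared by controls 4 and 5 and the day 28 arrays, beside which they lie on the principal components, was not tested and stays open. It would bear on the 347 calls and on the 243 day 10 calls still called at day 28. For day 10 against day 3, the 10 possible splits are too few for a share under 0.05 (6053 calls, highest other 9).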

How the results depend on the processing

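The offset of 16, the 50th percentile filter, controls 1 to 3 alone and the pairs of controls were chosen only after the data were seen. Counts are of probes called unless lists are named. Of the values of named genes under alternatives, 2229 kept their side of the threshold, 72 lost their call, 8 gained one and 0 reversed. Of the list values, 2619 kept their side, 115 lost and 45 gained a call, and 1 reversed: macrophage and monocyte markers at day 2, median -0.04 and not called, were at 0.40 with controls 1 to 3 alone. The median alone changed sign, since the mean (0.11) and the direction of the list test were already upward. Over the pairs of controls, all of the same number, that median ran from -0.50 (controls 4 and 5) to 0.46 (controls 2 and 3), so that its sign follows which controls are used. Of 217 list tests 24 had a median, mean and test direction that differed in sign, 0 of them called.

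With the replicate number as a block, day 28 against control gave 816 calls and 600 day 10 calls still called at day 28. Replicate number 5 occurs among the controls alone, so the block takes control 5 out of the comparison. Leaving out control 5 gave 772 calls and 567 still called. Replicate numbers do not pair the samples: 5 of 19 arrays had their closest array of another group under the same number. Deviations of the 33 same-number pairs correlated between -0.16 and 0.13. With array weights the counts were 1583 for day 28, 5669 for day 3 against day 2 and 1085 still called. Controls 4 and 5 had weights of 0.55 and 0.62, and day 3 replicate 3 a weight of 4.10. An offset of 16 gave 222 for day 28 and 160 still called. Controls 1 to 3 alone gave 731 for day 2, 1874 for day 28, 1338 still called and 643 shared by days 2 and 3. The cause was not tested for the counts with array weights, an offset of 16 or controls 1 to 3 alone. Requiring at least 2-fold lowers counts by construction: day 2 144, day 3 1292, day 10 2134, day 28 69, day 28 against day 10 1608, day 3 against day 2 699 and day 10 against day 3 1837. With the 2-fold threshold on the day 10 calls alone, and none on the later comparison, 2012 were called back by day 28 and 136 still called. The estimated correlation, which exceeded the preset one in 210 of the 217 list tests, left 0 lists at day 2, 0 at day 3, 0 at day 10, 1 at day 28, 5 for day 28 against day 10, 0 for day 3 against day 2 and 0 for day 10 against day 3.

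Leaving out 1 array gave 814 to 1241 calls at day 2, 4234 to 5262 at day 3, 5766 to 6870 at day 10, 105 to 772 at day 28, 4598 to 5325 for day 28 against day 10, 2241 to 3924 for day 3 against day 2 and 5007 to 5826 for day 10 against day 3. It left 3997 to 4945 called back, 75 to 567 still called, 620 to 1096 shared by days 2 and 3, and 2030 to 2806 by days 3 and 10. Lists called ranged over 4 to 6, 11 to 17, 17 to 21, 13 to 16, 18 to 19, 12 to 15 and 12 to 14 in the same order. Over the 10 pairs of controls, calls were 311 to 1892 at day 2, 3882 to 4674 at day 3, 5148 to 6264 at day 10 and 29 to 1312 at day 28.

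Background limits the dim genes: without detection calls, a value below the median of all probes (log2 6.83) cannot be told from background here, and without background correction the fold of Arg1 at day 10 was 18.9. Scaling arrays to a common median moves nothing on values already quantile-normalized, a stricter filter on detection p-values needs the table that was not used, and no slide is given, so these were not run.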

Other observations

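The genes given per array and the probes without a symbol were chosen after their values were seen.

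Clock genes differed between arrays in ways the groups only partly follow. Arntl, a core clock activator, lay at 7.69 to 8.26 in controls 1 to 3 and at 6.74 to 6.96 in controls 4 and 5, beside 6.79 to 6.86 at day 28 and 8.04 to 8.90 on the arrays of days 2, 3 and 10. Dbp, a clock output gene, lay at 11.7 to 12.9 in control, 10.6 to 11.8 at day 2, 9.14 to 11.1 at day 3, 9.52 to 9.83 at day 10 and 12.4 to 12.8 at day 28. The clock list was not called at day 2 (3 up, 2 down of 14, adjusted p = 0.84) or day 28 (1 up, adjusted p = 0.767). The atrial genes Sln and Myl7 also spread within groups, Myl7 from 6.99 to 11.4 in control, 10.6 to 12.4 at day 3 and 6.68 to 7.89 at day 10.

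Detoxification and proteostasis genes changed in parts of their lists. Of 22 NRF2, metallothionein and xenobiotic genes, 6 rose and 6 fell at day 3 (adjusted p = 0.766) and 9 rose and 9 fell at day 10 (adjusted p = 0.961), with Srxn1 at 2.22, the glutathione transferases Gsta1 at -1.92 and Gsta3 at -2.05 at day 3, and Gclm at 1.63 at day 10. Of 21 heat shock genes, 8 rose and 3 fell at day 3 (adjusted p = 0.0701), with Hspa1l at 3.08 and Hspb1 at 1.74. Autophagy and muscle protein breakdown genes had 4 rises and 10 falls among 27 at day 10, with Map1lc3b at -1.51 (adjusted p = 0.101). Glucocorticoid targets went both ways at day 10, 5 up and 5 down of 13 (adjusted p = 0.961). Lymphocyte markers (2 of 12 called at day 10, adjusted p = 0.161), adipocyte markers (1 of 5, adjusted p = 0.592) and erythroid markers (2 of 6, adjusted p = 0.358) were not called as lists at day 10.

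At day 28 against control, 5 further lists passed at the preset correlation with 0 or 1 called members: sarcomere genes (adjusted p = 0.0223, and adjusted p = 0.366 with an estimated correlation), TCA cycle genes (0.0248, and 0.642), cell cycle genes (0.0223, and 0.63), heat shock genes (0.0121, and 0.366) and erythroid markers (0.0223, and 0.366). Calls among these ended when 1 array was left out. Sarcomere genes lost theirs without control 2 (0.061) or day 28 replicate 1 (0.0576), and TCA cycle genes without control 3 (0.0868) or day 28 replicate 2 (0.0618). Cell cycle genes lost theirs without control 1 (0.0772), control 3 (0.0731) or day 28 replicate 4 (0.0531), and erythroid markers without control 5 (0.118) or day 28 replicate 1 (0.128). Heat shock genes at day 3 were called without control 1 (0.037) or control 3 (0.0391), and those at day 2 (adjusted p = 0.0994) without control 1 (0.0393). Without the filter on dim probes, heat shock genes were called at day 3 (0.0378) and day 2 (0.0473), and cell cycle genes at day 28 were not (0.113). Erythroid markers at day 28 were not called with the replicate number as a block (0.0992) or controls 1 to 3 alone (0.0873).

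The probe ILMN_2690603, which has no symbol, rose by 6.94 at day 10 and fell by 6.35 from day 10 to day 28, and ILMN_2735350 rose by 4.77 at day 3.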
